A study of Mus musculus with 5 samples.

How the data were processed

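RNA was sequenced from liver metastases of CT26 mouse colon carcinoma cells in BALB/c mice, in 2 libraries from mice given an antibody against PD-1 (antibody alone) and 3 libraries from mice given the antibody and dasatinib (combination). Per the labels' protocols, RNA was isolated with a column kit and libraries were made from 3 ug of total RNA with a SMARTER mRNA kit. Reads were aligned with HISAT2 2.1.0 and Bowtie2 2.3.4.3 to GRCm38.p6, per the submitters' processing notes. The program that turned alignments into gene values, its annotation, and any handling of strand or of reads shared by several genes are not given in the sources used here.

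The deposited tables hold 1 FPKM value per gene (fragments scaled by transcript length and by the mapped fragments of the library), computed by the authors and written to 2 decimals, for the same 17306 mRNA genes in each library. No counts were used here, so the planned count test gave way to the test planned for a normalized unit. A single line without a gene was left out of each library. A total of 26 gene symbols that a spreadsheet had turned into dates were restored from the gene identifier, using the names in the reference tables of genes. FPKM sums ran from 532855 to 588331 per library, and no pair of libraries was identical. Paralogs with near-identical sequence, such as Oas1a and Oas1g, Ifit3 and Ifit3b, Hba-a1 and Hba-a2, Tgtp1 and Tgtp2, or the Ccl21a group, may share reads, so their single values are uncertain.

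Depth was estimated from the steps between low FPKM values of genes with 1 annotated transcript of 300 to 1500 nucleotides, where 1 fragment adds a fixed amount. For each library a range of depths was tried and the value that best turned low values into whole fragments was kept. It gave 18400000 and 17200000 fragments for antibody alone and 19000000, 18900000 and 18700000 for the combination. Between 78.0% and 81.2% of the values then lay within 0.2 of a whole fragment, against 40% for values spread evenly. The depth and a length offset had been chosen for this closeness, so 40% is too low a reference. A score of closeness to whole fragments was 0.597 to 0.632 in the libraries. In 20 shuffles per library, with the depth alone chosen anew, it reached at most 0.262. The share of values near a whole fragment was too small to treat the values as counts. A fold change of a gene near 1 FPKM is imprecise at this depth, and the log scale used here understates it.

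Genes with at least 1 FPKM in at least 2 libraries were kept, which left 11936 and set 5370 aside; this filter was set after the tables had been seen and before any test was run. The log2(FPKM + 1) values of all 5 libraries were fitted with limma 3.58.1 in R 4.3.3, with treatment as the only term, an intensity trend in the variance, and 3 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are differences of log2(FPKM + 1), combination minus antibody alone. They are given with their standard error (SE), and FPKM means with the SD over libraries.

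Before the data were examined, 45 gene lists were fixed for pathways and for the cell types that an excised liver metastasis could hold. They contain 876 entries, of which 45 had no row to match, among them every mitochondrially encoded gene. Lists with at least 5 tested genes, 36 in all, were tested with camera (limma) at a preset correlation of 0.01 between genes, which asks whether a list's fold changes differ from those of the other genes. Camera with the correlation estimated per list, and fry, which asks whether the list's genes move on balance in a single direction, were alternatives. Terms of GO, KEGG and Reactome that the deposited tables attach to genes were tested in the same way when they held 15 to 300 tested genes, which gave 2133 terms. The share of summed FPKM taken by each of 22 cell type lists was compared with an exact two-sided permutation test. The 10 possible splits of 5 libraries into 2 and 3 allow no p below 0.1.

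The genes named were set by a rule fixed before the data were examined. It took the 12 largest changes per direction among genes past the threshold, with mean log2(FPKM + 1) of at least 1, groups that did not overlap, and a symbol that is not a predicted gene or pseudogene. It added the 4 leading members of each list past its test, the 3 leading members of the 5 leading terms per direction, and 20 genes chosen for the treatments. The rule had been written for log2 CPM, which log2(FPKM + 1) replaced. Other genes named in the text are called members of a list or examples chosen after their values were seen. Not every gene that the rule took is reported here.

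The test was tried on simulated data for this comparison, with 11936 genes of which 200 were changed, 20 times for each of 2 ways to draw the variances. With variances drawn from the fitted prior it recovered 62.5% of genes changed by 1 on the log2 scale and 96.3% of those changed by 2, and 4.3% of its calls were false. With each gene's own fitted variance, the corresponding values were 88.0%, 99.4% and 7.1%. The changed genes were drawn only from the more highly expressed of the tested genes, so the recovery does not cover genes near 1 FPKM. The changed list was found in 20 of 20 simulations of either kind, and an unchanged list was called in 1. Genes were simulated independently of each other, while the correlation estimated for the type I interferon list was 0.839. The simulations therefore do not show how often camera at the preset correlation calls lists whose genes vary together.

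Alternatives fixed beforehand were a pseudocount of 0.1, the replicate number as a block, the mean of the hepatocyte list as a covariate, removal of the hepatocyte and erythroid lists from the totals and tests, removal of each library in turn, and the other list tests. Removal of the hepatocyte and erythroid lists also scaled all libraries to the same total. Its effect on the tests cannot be told apart from that of this scaling. Alternatives chosen after the data had been seen were no filter, a stricter filter (1 FPKM in every library of a group), median-of-ratios and upper-quartile scaling, rescaling to TPM, quantile normalization, robust moderation, and shares without the most abundant member, or without the 2 most abundant, of each list. For the closing section, transcript length and GC content were taken from GENCODE M21 for 11787 of the tested genes. A spline trend of fold change on both was fitted over these genes. For the matrix list and a glucocorticoid-induced list only, its part was taken per member. Camera was run again for them with the trend removed from every library.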

Results

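Gene expression was measured by RNA sequencing in 5 libraries from liver metastases of CT26, a colon carcinoma cell line derived from BALB/c mice. The cells had been put into the spleen, and the metastases that formed in the liver were excised on day 14. In 2 libraries the animals had received an antibody against PD-1, an inhibitory receptor on T cells, on days 1, 7 and 13. In the other 3 libraries they had also received dasatinib, an inhibitor of SRC family, ABL, PDGF receptor and KIT kinases, daily from day 1 to day 13. The FPKM values implied depths of 17200000 to 19000000 fragments per library, and 11474 to 11765 genes reached 1 FPKM. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

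The first principal component of log2(FPKM + 1) held 55.5% of the variance and separated the treatments, with antibody alone at -27.7 and -28.5 and the combination at 21.1, 6.6 and 28.5. The second held 27.5% and set combination replicate 2 apart, at -30.9 against values from -4.9 to 15.8 for the other 4 libraries.

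**Figure D1:**
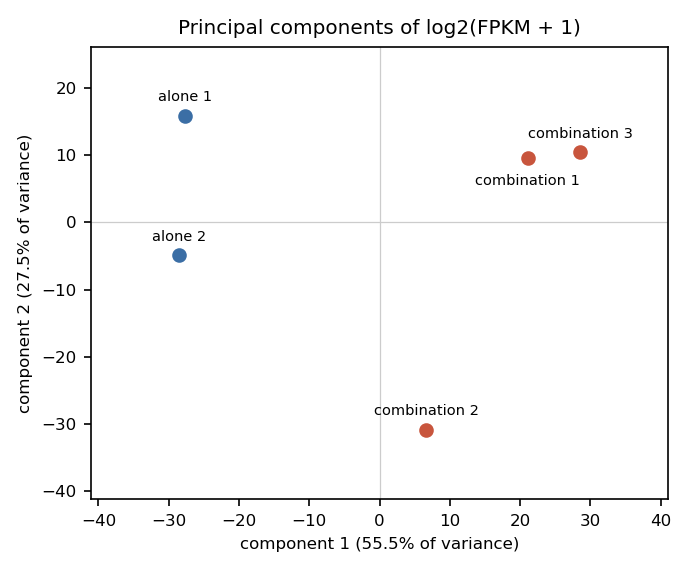
Principal components 1 (x axis, 55.5% of the variance) and 2 (y axis, 27.5%) of log2(FPKM + 1) over 11936 genes, 1 point per library, with antibody alone in blue and the combination in red. Component 1 parts the groups, and combination replicate 2 lies apart on component 2 at -30.9.

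The comparison asks how adding dasatinib to anti-PD-1 antibody changed gene expression in the metastases. Lists of interferon-stimulated, antigen presentation and chemokine genes were higher under the combination with camera at a preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.567 for each). Oas1a, an antiviral enzyme induced by interferon, rose from 6.69 ± 0.658 FPKM (SD, n = 2) to 54.4 ± 15.2 FPKM (SD, n = 3), and Cd74, the invariant chain of MHC class II, from 13.7 ± 2.91 to 109 ± 66.3 FPKM. Several genes of matrix, of alternatively activated macrophages and of liver enzymes were lower. Fn1, which encodes fibronectin, fell from 901 ± 179 to 348 ± 32.8 FPKM, and Arg1, an arginase on the macrophage list, from 120 ± 30.7 to 34.0 ± 10.6 FPKM. Cps1, the first enzyme of the urea cycle, fell from 59.0 ± 0.078 to 5.67 ± 3.00 FPKM.

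Of 11936 genes tested with limma, 155 rose and 76 fell at an adjusted p under 0.05, and 171 of these 231 changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 2656 genes. The groups did not overlap for 4913 genes (41.2%), where chance gives 20%. The share of calls that were higher was 67.1%, and it was 46.9% after median-of-ratios scaling, 44.0% after upper-quartile scaling and 48.6% after quantile normalization. These counts depended on the settings and on single libraries. Without a filter limma called 0 genes (3186 at an unadjusted p under 0.05), and the genes that rose were 53, 44 and 69 with the median-of-ratios, upper-quartile and quantile settings. No gene passed without antibody-alone replicate 1 (1749 at an unadjusted p under 0.05) or without antibody-alone replicate 2 (1811), where the lone library left was assumed to vary like the others. There were 132 calls without combination replicate 1, 1832 without combination replicate 2 and 49 without combination replicate 3.

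Interferon-stimulated genes rose together. Of 22 tested genes on the type I interferon list, 15 rose over all genes and 22 when adjusted over the list alone, with a median log2 fold change of 1.98 (camera adjusted p = 1.67e-17, and adjusted p = 0.567 with an estimated correlation). Oas1a (chromosome 5, 120896256 to 120907544, GRCm38.p6) changed by 2.82 ± 0.23 (log2, SE; limma adjusted p = 0.0146). Isg15, a ubiquitin-like protein, rose from 17.3 ± 1.76 to 108 ± 43.1 FPKM, and Usp18, its deconjugating enzyme, from 4.45 ± 0.113 to 33.9 ± 18.7 FPKM. Ifit3b, Ifit3 and Zbp1, a sensor of nucleic acids, changed by 2.86, 2.61 and 2.76 on the log2 scale. Oas1g and Apol9a, which are on no list, rose by 2.76 and 2.65. Of 22 tested genes on the interferon gamma list, 12 rose over all genes and 19 when adjusted over the list alone, with a median of 1.64 (camera adjusted p = 3.83e-13, and adjusted p = 0.567 with an estimated correlation). The GTPases Igtp and Tgtp2 rose by 2.24 and 2.59 on the log2 scale. Ido1 and Nos2, also on this list, stood at 0.01 each on the log2 scale. The highest value of Isg15, Usp18, Ifit3 and Zbp1 was in combination replicate 2, the library apart on the second component.

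Chemokine genes were part of the rise. Of 21 tested, 6 rose over all genes, and 13 rose and 1 fell when adjusted over the list alone, with a median of 1.04 (camera adjusted p = 2.02e-05, and adjusted p = 0.567 with an estimated correlation). The 6 were Ccl4, Ccl12, Cxcl10, Ccl21a, Ccl11 and Cxcl1. Ccl4 rose from 1.17 ± 0.368 to 13.3 ± 4.86 FPKM. Cxcl10, a ligand of CXCR3 on activated T cells, rose from 8.42 ± 0.226 to 42.7 ± 13.7 FPKM and is also on the interferon gamma list. Cxcl9, another CXCR3 ligand, stood at 0.26 ± 0.057 and 3.95 ± 3.01 FPKM and did not pass (limma adjusted p = 0.0795).

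Antigen presentation genes were higher in both classes. Of 9 tested MHC class II genes, 3 rose over all genes (Cd74, H2-Aa and H2-Ab1) and 8 when adjusted over the list alone, with a median of 2.13 (camera adjusted p = 3.63e-06, and adjusted p = 0.567 with an estimated correlation). H2-Aa rose from 4.93 ± 1.06 to 37.4 ± 21.8 FPKM. Dendritic cell genes took 0.0626% of the summed FPKM under antibody alone and 0.110% under the combination (exact permutation p = 0.1, the smallest possible, and 0.314 after Benjamini-Hochberg adjustment over the 22 cell type lists). Bst2, a gene known to be induced by interferon but on neither interferon list, carried most of this difference, and without it the shares were 0.0388% and 0.0403% (exact permutation p = 0.8). Without Bst2 and Fscn1 they were 0.00834% and 0.0102% (exact permutation p = 0.1). Of 16 tested MHC class I presentation genes, 3 rose over all genes and 8 when adjusted over the list alone, with a median of 0.55 (camera adjusted p = 2.02e-05, and adjusted p = 0.567 with an estimated correlation). The 3 were the immunoproteasome subunits Psmb8, Psmb9 and Psmb10, and Psmb9 rose from 9.50 ± 0.049 to 34.5 ± 11.9 FPKM. Genes of the class I molecules themselves did not pass over all genes. Among them H2-K1, H2-D1 and B2m stood at 0.41, 0.38 and 0.26 on the log2 scale (limma adjusted p from 0.468 to 0.646).

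**Figure D2:**
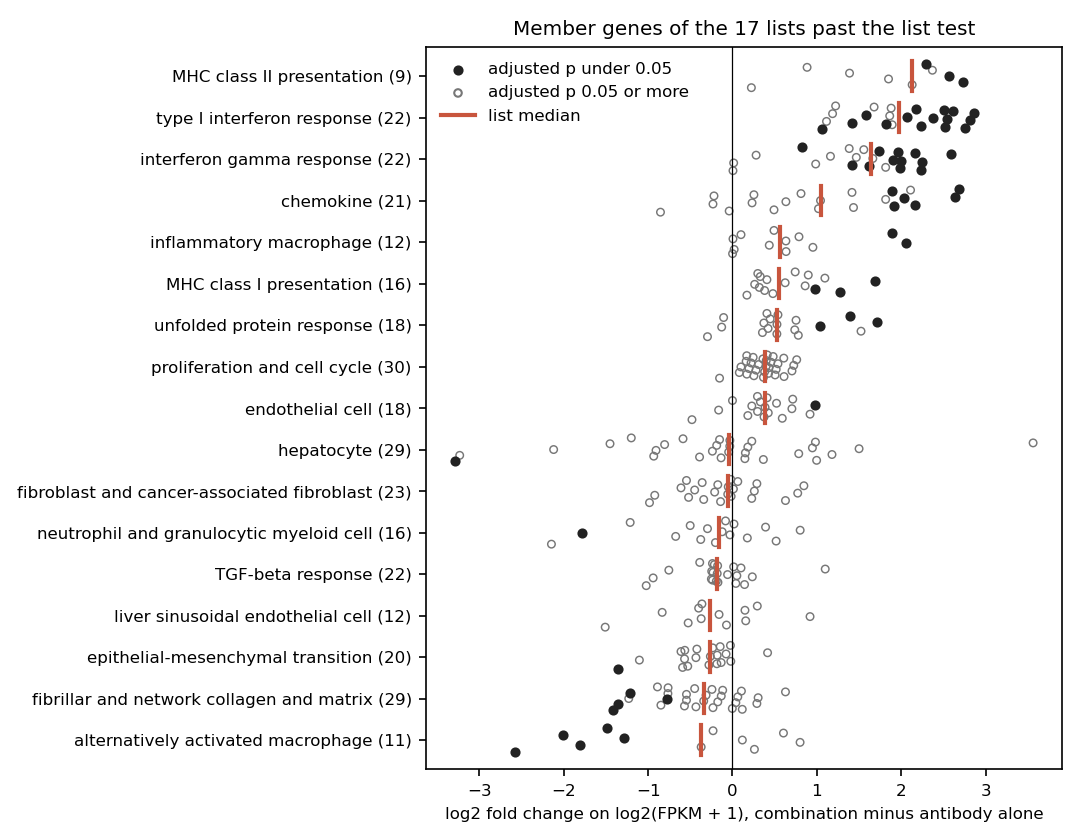
Log2 fold change on log2(FPKM + 1), combination minus antibody alone (x axis), of each tested member of the 17 lists past the camera test at a preset correlation (y axis, number of tested members in brackets). Filled points are genes with an adjusted p under 0.05, open points are other genes, and red bars are medians, which run from -0.37 for alternatively activated macrophages to 2.13 for MHC class II.

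Macrophage genes went both ways. Of 11 tested genes of alternatively activated macrophages, 5 fell over all genes, and 5 fell and 2 rose when adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.000902, and adjusted p = 0.567 with an estimated correlation). This list alone passed fry (adjusted p = 0.0253). The 5 were F13a1, a coagulation factor subunit made by macrophages, Chil3, Arg1, the haemoglobin scavenger receptor Cd163 and the mannose receptor Mrc1. The excised tissue also held liver transcripts such as Alb, and whether the fall of Arg1 came from macrophages or from other cells was not tested. F13a1 (chromosome 13, 36867178 to 37050244) fell from 26.0 ± 1.16 to 3.55 ± 0.787 FPKM (limma adjusted p = 0.00867). Of 12 tested genes of inflammatory macrophages, 2 rose over all genes and 6 when adjusted over the list alone, with a median of 0.56 (camera adjusted p = 0.00103, and adjusted p = 0.567 with an estimated correlation). They were Il1b, which encodes interleukin 1 beta and rose from 2.36 ± 0.311 to 12.9 ± 0.668 FPKM, and the neutrophil chemoattractant Cxcl1.

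The general macrophage and monocyte list did not pass as a whole (24 genes, median 0.29, camera adjusted p = 0.177). In it Fcgr1, Aif1, Ms4a7 and Ly6c2 rose and Cd163 and Mertk fell over all genes, and 6 rose and 4 fell when adjusted over the list alone. Its share of the summed FPKM was 1.21% ± 0.123 under antibody alone and 1.05% ± 0.0775 under the combination (exact permutation p = 0.1). Most of it was Spp1, and without that gene the shares were 0.282% and 0.354% (exact permutation p = 0.4). Of 12 tested Kupffer cell genes Cd5l rose, while the list did not pass (camera adjusted p = 0.270; 3 rose and 1 fell when adjusted over the list alone). Of 16 tested neutrophil genes, 1 fell over all genes and 3 when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0411, and adjusted p = 0.765 with an estimated correlation). It was Il1r2, the decoy receptor for interleukin 1, which fell from 15.1 ± 0.75 to 3.76 ± 1.20 FPKM, while S100a8 stood at 15.2 ± 3.68 and 14.5 ± 9.33 FPKM. The neutrophil call was lost in 7 alternative settings, among them those without a filter, with median-of-ratios, upper-quartile or quantile scaling, and without antibody-alone replicate 2 (median -0.09) or combination replicate 1 (-0.03), and the median was -0.46 without combination replicate 2.

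Matrix genes were lower as a group. Of 29 tested collagen and matrix genes, 4 fell over all genes and 6 when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 3.47e-06, and adjusted p = 0.567 with an estimated correlation). Beside Fn1 (chromosome 1, 71585473 to 71653234; -1.36 ± 0.17, log2, SE; limma adjusted p = 0.0306), the 4 were Col6a1, Col6a2 and Col5a3. Col6a1, a chain of collagen VI, fell from 156 ± 38.9 to 65.6 ± 1.38 FPKM. Col1a1, a chain of the main fibrillar collagen, stood at 175 ± 14.2 and 182 ± 12.1 FPKM (0.06 ± 0.13, limma adjusted p = 0.806). Fold changes over all genes went down with transcript length (Spearman -0.274 over 11787 genes, which are not independent replicates). The closing section takes this into account for the matrix list and a glucocorticoid-induced list only. It was not taken into account for any other list, such as those of epithelial-mesenchymal transition, the TGF-beta response or chemokines. The fibroblast list held 0.664% ± 0.0400 of the summed FPKM under antibody alone and 0.479% ± 0.0352 under the combination (exact permutation p = 0.1), with a median fold change of -0.06. S100a4 alone gave 0.383% and 0.247%, and without it the shares were 0.281% and 0.232% (exact permutation p = 0.2). None of its 23 tested genes passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0469, and adjusted p = 0.641 with an estimated correlation). That call was lost in 10 alternative settings, and the median ran from -0.25 without combination replicate 2 to 0.04 without combination replicate 1.

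Of 20 tested genes of epithelial-mesenchymal transition, 1 (Fn1) fell over all genes and 4 when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 1.01e-05, and adjusted p = 0.567 with an estimated correlation). S100a4 stood at 2120 ± 53.5 and 1392 ± 124 FPKM (limma adjusted p = 0.0992). No gene of the 22 tested of the TGF-beta response passed over all genes or when adjusted over the list alone, and their median was -0.19 (camera adjusted p = 0.0122, and adjusted p = 0.641 with an estimated correlation). The call was lost without antibody-alone replicate 2 (median -0.15). Genes of matrix proteases and their inhibitors split, and the list did not pass (24 genes, median -0.26, camera adjusted p = 0.0545). Mmp13, Mmp12 and the urokinase gene Plau rose, and Mmp19 and the inhibitor Timp3 fell, with 4 up and 7 down when adjusted over the list alone. Mmp13 rose from 1.22 ± 0.325 to 8.54 ± 1.55 FPKM, and Timp3 fell from 90.2 ± 2.39 to 31.6 ± 5.96 FPKM.

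The kinases that dasatinib is known to inhibit did not move as a list (20 genes, median 0.10, camera adjusted p = 0.973), and none passed over all genes, while 1 rose and 1 fell when adjusted over the list alone. Pdgfra stood at 34.6 ± 11.9 and 16.6 ± 2.04 FPKM (-0.98 ± 0.22, limma adjusted p = 0.0746) and Pdgfrb at 28.2 ± 4.91 and 19.3 ± 2.65 FPKM (-0.52 ± 0.17, adjusted p = 0.142). Src stood at 44.9 ± 3.58 and 45.7 ± 5.68 FPKM, Csf1r at 16.98 ± 2.31 and 20.2 ± 5.25 FPKM, and Ddr2 at 35.8 ± 8.79 and 28.7 ± 5.07 FPKM. Kit stayed under the filter at 0.39 ± 0.141 and 0.893 ± 0.344 FPKM. The stromal genes Fap and Acta2 did not pass, at 11.6 ± 1.78 and 5.91 ± 2.42 FPKM for Fap (limma adjusted p = 0.142) and 28.3 ± 3.45 and 24.8 ± 6.59 FPKM for Acta2 (adjusted p = 0.595). Without antibody-alone replicate 1 the Pdgfra value was -0.64.

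Endothelial genes were slightly higher. Of 18 tested, 1 rose over all genes and 1 when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.0129, and adjusted p = 0.715 with an estimated correlation). It was Sox18, a transcription factor of vessels, which rose from 3.77 ± 0.085 to 8.39 ± 0.480 FPKM. The list call was lost without antibody-alone replicate 1 (median 0.27) or combination replicate 2 (0.32). None of 12 tested genes of liver sinusoidal endothelium passed over all genes, 3 fell and 1 rose when adjusted over the list alone, and the median was -0.26 (camera adjusted p = 0.0465, and adjusted p = 0.648 with an estimated correlation). Lyve1, a hyaluronan receptor, stood at 29.4 ± 7.35 and 10.01 ± 4.26 FPKM (limma adjusted p = 0.0618). This call was lost in 10 settings, among them those without antibody-alone replicate 2 (median -0.05), combination replicate 1 (-0.28) or combination replicate 2 (-0.19).

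A few liver enzyme genes fell steeply. Cyp2b10, a cytochrome P450 of drug metabolism (chromosome 7, 25897658 to 25926624), had 11.4 and 16.7 FPKM under antibody alone and 0.14, 0 and 0.49 FPKM under the combination (-3.63 ± 0.24, log2, SE; limma adjusted p = 0.00867). Cps1 (chromosome 1, 67111750 to 67231267) fell by 3.29 ± 0.39 on the log2 scale (adjusted p = 0.0272). Sult1e1, an oestrogen sulfotransferase, fell from 7.10 ± 0.304 to 0.353 ± 0.319 FPKM and Cyp17a1, an enzyme of steroid synthesis, from 12.4 ± 7.03 to 1.16 ± 0.850 FPKM. Of 29 tested hepatocyte genes, Cps1 alone fell over all genes, 6 fell and 1 rose when adjusted over the list alone, and the median was -0.05 (camera adjusted p = 0.0465, and adjusted p = 0.802 with an estimated correlation). Alb, which encodes albumin, stood at 5595 ± 1325 and 3006 ± 740 FPKM (limma adjusted p = 0.129). Hepatocyte genes took 2.89% ± 0.428 and 2.36% ± 0.787 of the summed FPKM, with the lowest share, 1.52%, in combination replicate 2 (exact permutation p = 0.4). Without Alb the shares were 1.89% and 1.83% (exact permutation p = 0.9). The hepatocyte call was lost in 8 alternative settings. They were those without that library (median 0.17), without antibody-alone replicate 2 (0.03), with the hepatocyte covariate (0.01), without a filter, and with median-of-ratios, upper-quartile, TPM or quantile scaling. The median was -0.32 without combination replicate 3.

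Of 23 tested genes of xenobiotic metabolism, Cyp2b10 alone fell over all genes and 3 fell when adjusted over the list alone. That list's median was 0.02, its mean -0.12 and its test direction down, and it did not pass (camera adjusted p = 0.106). Of 20 acute phase genes, Il1rn, Steap4 and Saa4 rose and Serpina3n fell, 4 rose and 2 fell when adjusted over the list alone, and the list did not pass (median 0.31, camera adjusted p = 0.106). Il1rn, the interleukin 1 receptor antagonist, rose from 2.17 ± 0.481 to 11.6 ± 3.16 FPKM, and Serpina3n fell from 616 ± 74.6 to 289 ± 47.5 FPKM.

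**Figure D3:**
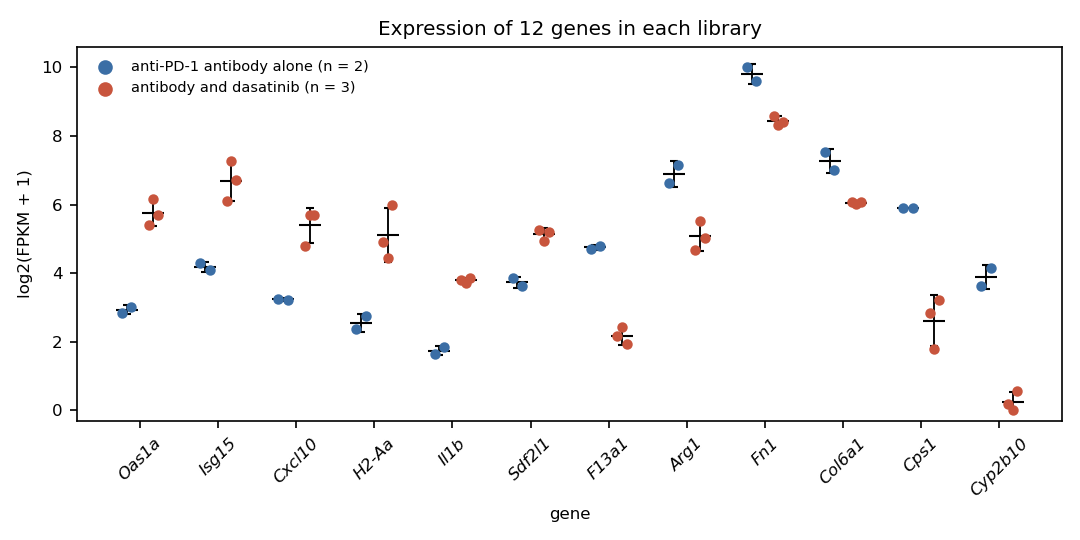
Expression as log2(FPKM + 1) (y axis) of 12 genes (x axis), 1 point per library, for antibody alone (blue, n = 2) and the combination (red, n = 3), with bars for mean and SD. In all 12 genes the groups do not overlap, as in 41.2% of all tested genes. For Oas1a, H2-Aa, F13a1, Cps1 and Cyp2b10 this was a condition of the rule that named them. Cyp2b10 lies between 0 and 0.49 FPKM in the combination libraries.

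Genes of the unfolded protein response were higher. Of 18 tested, 3 rose over all genes and 7 when adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.000144, and adjusted p = 0.567 with an estimated correlation). They were Sdf2l1 and Creld2, residents of the endoplasmic reticulum, and Chac1, a glutathione-degrading enzyme. Sdf2l1 rose from 12.4 ± 1.49 to 34.2 ± 4.13 FPKM. None of 30 proliferation genes passed over all genes or when adjusted over the list alone, though 29 were above 0, with a median of 0.39 (camera adjusted p = 0.000383, and adjusted p = 0.786 with an estimated correlation). Mki67, a marker of cycling cells, stood at 15.8 ± 2.14 and 18.1 ± 3.62 FPKM (limma adjusted p = 0.643). The proliferation call was lost without antibody-alone replicate 2 (median 0.20).

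Other genes with large falls were Mt3, a metallothionein, from 20.9 ± 2.28 to 2.86 ± 1.16 FPKM, Chrna1, a subunit of the muscle acetylcholine receptor, from 17.03 ± 3.71 to 3.79 ± 0.647 FPKM, and Arl4d, a small GTPase, from 30.4 ± 1.64 to 7.81 ± 1.15 FPKM. Sult1d1, Gng4 and Itga10 fell by 1.99, 1.83 and 1.68 on the log2 scale.

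Several lymphocyte genes were near the floor in all 5 libraries. Cd8a stood at 0.065 ± 0.007 and 0.297 ± 0.096 FPKM, Pdcd1, which encodes PD-1, at 0.105 ± 0.106 and 0.17 ± 0.052, Ifng at 0.050 ± 0.071 and 0.047 ± 0.045, and Foxp3 at 0.025 ± 0.007 and 0.050 ± 0.030. These genes were under the filter and were not tested, and at this depth such values rest on few fragments. Other members of the lymphocyte lists were higher in all 5 libraries, among them Thy1 (13.3 to 32.1 FPKM), which is also on the fibroblast list, Ccl5 (30.4 to 117 FPKM) and Xbp1 (59.0 to 89.3 FPKM). Gzmb, a granzyme of cytotoxic cells, stood at 0.145 ± 0.092 and 1.73 ± 0.795 FPKM (limma adjusted p = 0.0791), and Cd274, which encodes PD-L1, at 0.805 ± 0.021 and 2.69 ± 1.12 FPKM (adjusted p = 0.102). Of 10 tested checkpoint genes Lgals9 rose, from 49.6 ± 8.90 to 111 ± 18.4 FPKM, and 2 rose when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.187). Of 3 tested cytotoxic and NK genes Ccl4 rose over all genes and 3 rose when adjusted over the list alone. Of 1 tested T cell gene, Thy1, 3 B cell genes and 3 regulatory T cell genes, none passed over all genes, and 1, 1 and 0 rose when adjusted over the list alone.

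The remaining lists did not pass camera. None of their members passed over all genes in dendritic cells (adjusted p = 0.187; 3 rose and 1 fell when adjusted over the list alone), hypoxia and glycolysis (26 genes, median -0.14, adjusted p = 0.0541; 0 adjusted over the list alone), hepatic stellate cells (0.107; 0), p53 and apoptosis (0.554; 0), cholangiocytes (0.683; 1 fell), adipocytes (0.787; 0), platelets (0.819; 0), YAP and SRF targets (0.970; 0), pericytes (0.973; 0), or angiogenesis factors (0.973; 2 rose and 1 fell). Of lymphatic endothelial genes Ccl21a rose (camera adjusted p = 0.312; 1 rose and 1 fell when adjusted over the list alone), and of immediate early and heat shock genes Hsph1 rose (0.973; 1 and 1). The camera direction, relative to all genes, was down while the median, the mean or both were above 0 for the lymphatic, p53, cholangiocyte, adipocyte, platelet, YAP and SRF, angiogenesis, pericyte and immediate early lists. Of 4 tested erythroid genes none passed over all genes, and 3 fell and 1 rose when adjusted over the list alone. Erythroid genes took 0.336% ± 0.0114 and 0.131% ± 0.0816 of the summed FPKM (exact permutation p = 0.2), of which Hba-a1 and Hba-a2 made up 98.7% and 97.5%. Without these 2 genes the shares were 0.00444% and 0.00329% (exact permutation p = 0.1). None of 2 mast cell genes, 2 pancreatic genes and 1 skeletal muscle gene passed over all genes or when adjusted over the list alone.

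Among 2133 annotated terms, 94 were higher and 69 lower with camera at the preset correlation, and none passed with an estimated correlation. The fall of fold changes with transcript length over all genes was not taken into account for any term. Cellular response to interferon-beta led the higher terms (34 genes, 10 rose, median 0.88, adjusted p = 1.02e-10, and adjusted p = 1 with an estimated correlation). Mitochondrial translation came next among distinct themes (87 genes, median 0.27, adjusted p = 3.7e-06, and adjusted p = 1 with an estimated correlation), with no member past the threshold. Its leading members Mrps10, Mrpl12 and Mrpl28, of the mitochondrial ribosome, stood at 0.61 ± 0.13, 0.62 ± 0.13 and 0.51 ± 0.11 (log2, SE; limma adjusted p from 0.0627 to 0.0652). Extracellular matrix led the lower terms (141 genes, 8 fell and 2, Mmp12 and Mmp13, rose, median -0.25, adjusted p = 9.63e-06, and adjusted p = 1 with an estimated correlation).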

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

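The settings without a filter, with a stricter filter, with another scaling, with robust moderation and with the most abundant member left out of each share were chosen after the data had been seen. Named genes kept their direction and side of the threshold in 1176 of 1496 recomputed values, with 226 no longer past it, 78 newly past it and 16 reversed. Lists past the threshold kept their call in 232 of 271 values from camera at the preset correlation, a tally without the 2 other list tests given below. All 20 cell type shares moved by less than their spread when liver and erythroid genes left the total. Those genes held only a few percent of the total, so leaving them out could move the other shares little. Leaving out each list's most abundant member moved 12 of 22 shares by more than their spread. Against 155 genes higher and 76 lower, median-of-ratios scaling gave 53 higher, upper-quartile scaling 44 and quantile normalization 69. Without a filter limma called 0 higher and 0 lower (3186 at an unadjusted p under 0.05, smallest adjusted p 0.0722). The hepatocyte covariate gave 606 and 276. Against 8 lists lower, there were 4 under each of median-of-ratios, upper-quartile and quantile scaling, and 5 with liver and erythroid genes left out, after rescaling to TPM and without a filter. Terms lower were 44 without a filter, against 69. With estimated correlation, 0 lists and 0 terms passed in either direction, and fry passed 0 lists higher and 1 lower. Leaving out 1 library gave 0 to 1226 genes higher, 0 to 606 lower, 3 to 13 lists lower, 55 to 163 terms higher and 44 to 120 lower. The causes of these differences were not tested. Smaller sample sizes alone do not account for the 1226 genes higher and 606 lower, which came without combination replicate 2.

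The replicate number as a block gave 133 genes lower and 223 higher, and shared deviations correlated at 0.38 for number 1 and 0.34 for number 2. The deviations of the 2 antibody-alone libraries mirror each other, so these correlations are not separate evidence of pairing. With only 2 shared numbers, the replicate numbers were not taken to pair animals. The block turned S100a8 to 0.043, and with it the neutrophil and fibroblast lists did not pass (camera adjusted p = 0.0672 and 0.088).

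Values that changed direction were those of 3 genes that had not passed and of the hepatocyte list, which had passed (camera adjusted p = 0.0465) and did not without combination replicate 2 (adjusted p = 0.957). The fibroblast median changed sign too, from -0.06 to 0.04 without combination replicate 1, while its camera direction stayed down. Src, at 0.02, was -0.014 with the hepatocyte covariate, -0.02 with liver and erythroid genes left out, -0.054 with median-of-ratios, -0.064 with upper-quartile, -0.01 with TPM and -0.053 with quantile scaling, and from -0.072 to 0.102 with 1 library left out. Col1a1, at 0.06, was -0.011, -0.021 and -0.053 with median-of-ratios, upper-quartile and quantile scaling, and from -0.02 to 0.15 with 1 library left out. S100a8, at -0.20, ran from -0.663 to 0.043, and the hepatocyte median, at -0.05, from -0.32 to 0.17. The planned count tests, count filters and count normalizations were not run, since the unit was FPKM. At the implied 17200000 to 19000000 fragments, genes under 1 FPKM rest on few fragments and were mostly not tested.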

Other observations

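Tests of a single library, of macrophages, of liver tissue, of fibroblasts, of other splits and of the part that a length and GC trend gives were chosen after the values they use had been seen, and those of list medians after removal of that trend, of sex and of glucocorticoid-induced genes before.

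Several transcripts of cytotoxic cells were low in all 5 libraries (genes chosen after their values were seen). As a list, cytotoxic effector and NK genes took 0.00613% and 0.0167% of the summed FPKM (exact permutation p = 0.2, and 0.367 after Benjamini-Hochberg adjustment). The chemokine genes Ccl5 and Ccl4 made up 97.3% and 90.8% of that. The shares were 0.000377% and 0.00388% without Ccl5 (exact permutation p = 0.1) and 0.000167% and 0.00154% without both (exact permutation p = 0.2). Most untested genes on the lymphocyte and checkpoint lists had a higher mean under the combination. Lck had 0.275 and 0.953 FPKM, and Prf1 0.015 and 0.313 FPKM. Those with a lower mean were Cd160, Cd28, Eomes, Ifng, Il10, Tox and Ubash3a. Eomes had 0.235 and 0.077 FPKM, and Cd160 0.07 and 0.017 FPKM. Cd3e was listed at 0 in both antibody-alone libraries and had 0.23, 0.23 and 0.35 FPKM in the combination libraries. Nkg7, a granule protein of cytotoxic cells, had 0.07 and 0 against 0.84, 0.91 and 2.1 FPKM. Gzmc, Gzmd, Gzme and Gzmf, a cluster of related granzymes, had 1.45, 0.24, 0.43 and 0.87 FPKM in combination replicate 2 and were listed at 0 in the other 4 libraries. Hamp, which encodes the iron hormone hepcidin, had 0.32 and 0.17 FPKM under antibody alone and 8.10, 1.56 and 135 FPKM under the combination (limma adjusted p = 0.215). Alas2, the first enzyme of haem synthesis in erythroid cells, had 16.6 and 16.1 against 3.43, 8.09 and 2.68 FPKM (adjusted p = 0.0662). DNA replication genes were higher as a term (107 genes, median 0.28, camera adjusted p = 0.00037, and adjusted p = 1 with an estimated correlation). The 1 member that rose was Samhd1, a dNTP hydrolase with antiviral activity.

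Interferon-stimulated genes were higher under the combination, with a type I list median of 1.98 (camera adjusted p = 1.67e-17, and adjusted p = 0.567 with an estimated correlation). The lowest median with 1 library left out was 1.73, so no single library carried the rise. A larger share of macrophages and monocytes as a whole was argued against by the median of their list, 0.29 (95% bootstrap interval over members 0.12 to 0.63). This interval and those below resample genes measured in the same libraries. Such genes are not independent replicates, and the intervals leave out the spread between libraries. In the macrophage and monocyte list Fcgr1, Aif1, Ms4a7 and Ly6c2 rose and Cd163 and Mertk fell over all genes. A median over such members cannot show a change in the mix of these cells, so that explanation stays open. Less liver tissue was argued against by the median of 1.92 with the hepatocyte covariate. A response to interferon in the combination tumours is a hypothesis that stays open, and which cells carried it was not tested.

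Matrix genes were lower, with a list median of -0.34. A trend on transcript length and GC content gave -0.114 of it (interval -0.149 to -0.072), and with the trend removed the median was -0.28 and the list stayed lower (camera p = 0.000111, and p = 0.155 with an estimated correlation). This argues against the trend as the whole cause, while a part stays open, since the interval after removal, -0.45 to -0.04, reaches past the midpoint between 0 and the list median. Non-matrix fibroblast genes had a median of -0.14 (interval -0.61 to 0.01), which also reaches past it, so fewer fibroblasts cannot be told apart from a change in matrix expression here.

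For the lower levels of Cyp2b10, Cps1, Sult1e1 and Cyp17a1, less liver tissue as the whole cause was argued against by the other hepatocyte genes. Their median was -0.039 (interval -0.31 to 0.21), against -3.29 for Cps1. Over the whole list 17 genes were below 0, among them Cyp3a11 at -3.23 and Alb at -0.91, and 12 were above, up to 3.56 for Hamp. A median over such members cannot show a smaller loss of liver tissue, so that stays open. Animals of different sex were argued against by the highest Y-linked value, 0.07 FPKM, although only 1 of 4 listed Y-linked genes had a row. A weaker glucocorticoid signal may be a candidate explanation, since several liver enzymes depend on it. A list of glucocorticoid-induced genes was written before its values as a list were seen. However, Ddit4, Dusp1 and Cdkn1a were also on other lists tested here, so some of its values may already have been seen. Of its 16 genes 14 were below 0 and 1 fell over all genes (Fkbp5, limma adjusted p = 0.0433). The list median was -0.65 (interval -0.92 to -0.16, camera p = 6.24e-06, and p = 0.139 with an estimated correlation). The length and GC trend gave 0.055 (interval -0.006 to 0.087), on the other side of 0 from the list median. This argues against the trend as a cause of the fall in this list. With the trend removed the median was -0.67 (camera p = 2.1e-05, and p = 0.186 with an estimated correlation). The interval of that median, -0.89 to -0.23, reaches past the midpoint to 0, so the median after removal does not decide by itself. The list median was -0.39 without combination replicate 1. Hormone levels were not measured, and the hypothesis was found and tested on the same libraries, so the list gives no independent test.

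Of the 10 splits of the 5 libraries into 2 and 3, only 1, the real one, called as many as 231 genes with limma, and the highest of the other splits called 1. The splits are too few for a share under 0.05.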
